A study of Mus musculus and Homo sapiens with 64 samples.

How the data were processed

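The series measured H3K27ac, H3K4me1 and H3K4me3 by ChIP-seq in naive CD4+ T cells and in cells cultured toward the Th9 fate, at 4 stages in mouse (naive, days 3, 4 and 8) and in human (naive, days 5, 8 and 15). Of 64 samples, 48 had a peak list and 16 were inputs, which were not analysed here. Each stage had 2 replicates of each mark, grouped by the titles and characteristics of the labels.

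Per the submitters' processing notes, bcl2fastq 2.20.0.422, cutadapt 1.18, Picard 2.17.11, SAMtools 1.6, deepTools 3.0.1 and MACS2 2.1.1 were among the tools, with the builds mm10, GRCh38 and hg38, and per the series' design text peaks were called against input. The aligner and the calling options are not given in the sources used here. Each deposited list belongs to 1 library, without pooling of replicates, and has 9 columns in the layout of broad MACS2 peaks. The score of a peak in the deposited lists is 10 times its −log10 q, rounded down (99.99% of peaks or more in each list). The fold enrichment, a ratio over background, and the −log10 p and −log10 q values are the authors' own per peak, and the lowest deposited −log10 q was 2. Scores and folds were used to rank or filter peaks. The stricter score held all 8 lists of a species and mark to 1 threshold, the median −log10 q of their peaks together, which a deeper library passes more easily, and equal covered length ranked peaks within each list. A stray character before a chromosome name in 1 list was removed.

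Lists carry no read counts, so the depth per library is unknown. Its stand-ins are the number of peaks and the covered length, 80.4 to 126.1 Mb for mouse H3K27ac, 119.9 to 207.5 Mb for H3K4me1, 30.37 to 46.73 Mb for H3K4me3, and 63.97 to 128.5, 127.2 to 225.1 and 42.05 to 62.86 Mb in human. With 2 libraries per stage, and a peak threshold that turns weak signal into 0, a window covered at 0 is not shown to lack the mark. A deeper or better enriched library calls longer peaks, which centring, scaling and equal covered length address in different ways. Equal covered length keeps the shortest list of a species and mark whole and cuts the others at higher scores. Weak regions of that list can thus count as absent elsewhere.

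Mouse gene windows came from the RefSeq table of GRCm38.p6, the assembly of mm10, with 21631 protein-coding genes on the autosomes and chromosome X. As a check of the build, 62.0% of mouse H3K4me3 peaks lay within 2.5 kb of a gene end, against 19.5% with the ends moved by 100 kb. The window was the gene and 30 kb on each side for H3K27ac and H3K4me1. For H3K4me3 the design asked for a promoter window, but the table gives no strand, so 2.5 kb around both gene ends was used. No human annotation was used here, so human windows were tiles of 60 kb (5 kb for H3K4me3) on the 22 autosomes, and human genes, the overlap of changed genes between species and motif densities were not analysed here. Coordinates count from 1.

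The measurement was log2 of the covered bp in a window plus 200 bp. Each library was centred on its median over windows covered in all 8 libraries of that species and mark, and windows covered in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3, with 4 groups of 2 and eBayes with trend and robust settings. Calls are Benjamini-Hochberg adjusted p under 0.05 over the windows tested, and changes are on the log2(bp + 200) scale, which understates changes of short coverage. A change against libraries all at 0 depends on the pseudocount and is no bound, so bp are given for these. Because centring sets a long window's change relative to the median window, calls were also compared with raw covered bp.

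Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, each adjusted over the 17 lists: Th9 cytokines and receptors, Th9 transcription regulators, naive and resting T cell genes, activation genes, Th1 and cytotoxic, Th2, Th17, regulatory T cell, follicular helper, STAT targets and inhibitors, cell cycle, B cell, myeloid, NK and CD8 T cell, erythroid and platelet, housekeeping, and genes silent in T cells. With an estimated correlation camera takes its degrees of freedom from the few residual ones of this design. With a preset correlation it takes them from the number of windows. A call lost with the estimated correlation can therefore reflect the small design and does not by itself show correlation between genes. Some genes stand in 2 lists, such as Il4 and Ccl20. Named genes follow a rule: Il9 always, the 10 largest rises and 10 largest falls per H3K27ac comparison among windows past the threshold whose 2 later libraries both lay above (or below) both earlier ones, and up to 6 members per list by adjusted p. Neighbours that share peaks were counted together, under the gene with either end nearest to the changed peaks. By the same rule human tiles take the place of genes. Values of some genes are not reported here.

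Regions were made by merging the peaks of the 8 libraries of a species and mark. A region counted as gained at a step when both later libraries and neither earlier library had a peak overlapping it by at least 1 bp, and lost for the reverse. The same 4 libraries divided by replicate number, and crossed, gave the comparison level. Numbers of peaks and covered length were compared by exact permutation over 28 divisions of 8 libraries into 2 and 6. These tests, the lists, the rule for named genes and the alternatives were fixed before the data were examined, and the alternatives were other pseudocounts (50 and 1000 bp), no filter or at least 4 libraries, other windows (10 kb flanks, 5 kb promoters, tiles of 20 and 10 kb), no centring, scaling to total covered length, equal covered length, a stricter score, eBayes without robust and trend, 50% cover of a region, each library left out, and the replicate number as a block.

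Deviations of libraries with the same number were correlated to ask whether the numbers pair the samples. In mouse H3K4me3 all correlations between stages lay from 0.125 to 0.497, so the numbers may pair these libraries. Replicate 2 also had more H3K4me3 peaks than replicate 1 at every stage, so list size and pairing are not told apart. The block changed none of this mark's counts by over 1.5 times between the stages reported. No other mark had all its correlations over 0.1. All marks, mouse H3K4me3 too, were fitted as unpaired for the counts reported. The human titles carry the same 2 identifiers through all stages, but the labels do not say whether these mark donors, so human counts that the block moved by over 1.5 times are given with their blocked value.

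The limma step was tested on simulated data built from the real windows with 200 changed windows. It recovered 51 of 100 windows changed by 1 and 88 of 100 changed by 2 on the log2 scale for mouse H3K27ac (6 of 145 calls false), 53 and 87 for mouse H3K4me1 (7 of 147) and 76 and 88 for mouse H3K4me3 (12 of 176). For human H3K27ac it recovered 0 and 32 (1 of 33 false), for human H3K4me1 2 and 27 (2 of 31) and for human H3K4me3 40 and 52 (2 of 94). The simulated values were normal on the log2 scale, without a floor at 0 bp. Only 200 windows changed, while human H3K27ac had 4520 calls of 19577 tiles at day 5. Recovery in the data may therefore differ from these rates, and human changes of this size can be missed. The region step was tested on 1000 simulated windows, with 0 wrong lengths, and found 30 of 30 gained and 20 of 20 lost regions. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.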

Results

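The series followed 3 histone marks while naive CD4+ T cells were turned into Th9 cells, the helper subset named for making interleukin 9, in mouse and in human. H3K27ac marks active enhancers and promoters, H3K4me1 marks enhancers whether active or poised, and H3K4me3 marks promoters. Mouse naive CD4+ cells were stimulated through CD3 and CD28 with IL-4, TGF-β, IL-2 and an antibody to IFN-γ for 3 days. They were then kept in cytokines without the receptor stimulus to days 4 and 8. Human naive CD4+ cells were stimulated for 5 days with IL-1β added to the same kind of mixture, then kept without the stimulus to days 8 and 15. Each species thus had 4 stages with 2 replicates of each mark, 48 peak lists in all from 64 samples, and the 16 input samples were not analysed here. The labels do not say whether replicates came from separate animals or donors, so p-values measure only the spread between these samples, which may be technical. Values after ± are SD with n = 2 libraries unless another n is given.

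Mouse lists held 33370 to 51525 peaks for H3K27ac, 47859 to 77055 for H3K4me1 and 16835 to 23408 for H3K4me3. Human lists, read on the 22 autosomes, held 31040 to 80448, 46027 to 100957 and 20707 to 35002 peaks. Peak lists carry no read totals, so sequencing depth is unknown and the length covered by peaks stood in its place. The median Jaccard index of covered length in mouse H3K27ac was 0.743 within a stage and 0.484 between stages, and that of human H3K27ac was 0.672 and 0.480. The human day 5 H3K27ac libraries shared less, at 0.476, as did the mouse day 4 H3K4me1 libraries, at 0.566 against a median of 0.793 within a stage. Some lists stood apart from their partners. Human day 5 replicate 1 had 80448 H3K27ac peaks against 31891 in replicate 2 and 100957 H3K4me1 peaks against 66016. Human naive replicate 1 had 35002 H3K4me3 peaks against 22219, and mouse day 4 replicate 2 had 50161 H3K4me1 peaks against 75256 in replicate 1.

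**Figure D1:**
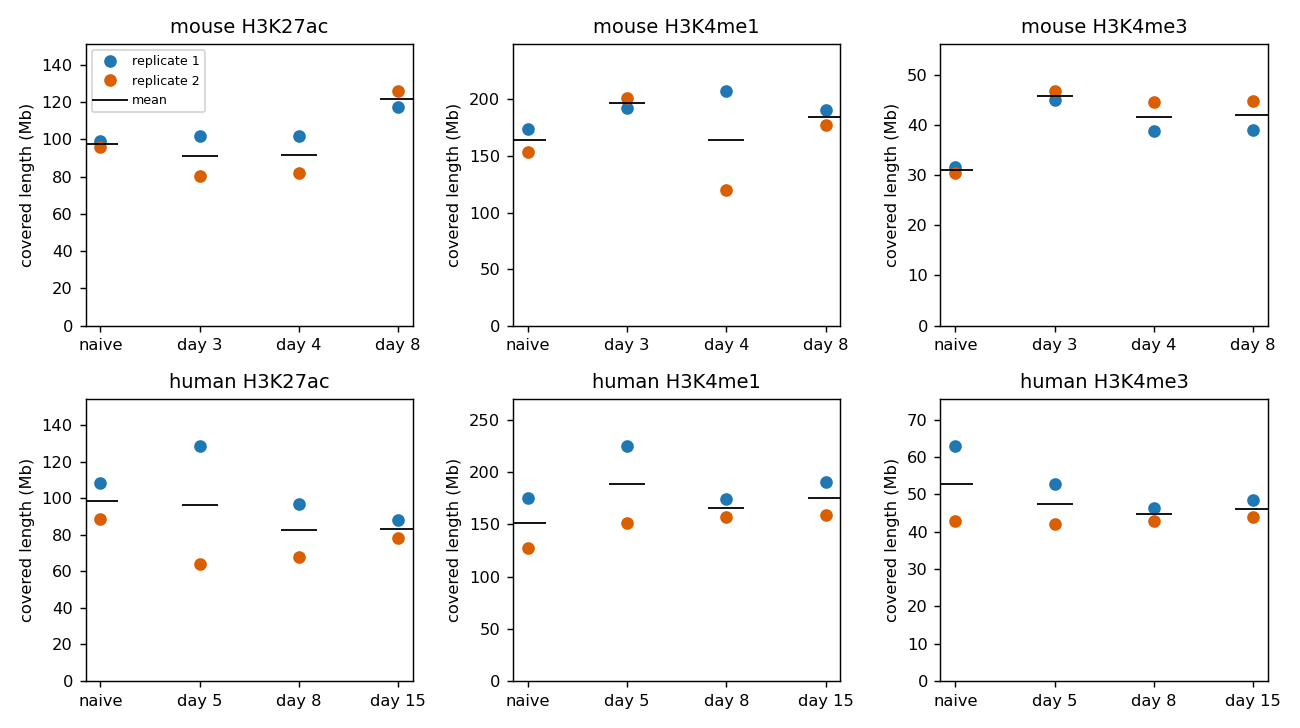
Length covered by peaks in each library (megabases, vertical axis) by stage for the 3 marks in mouse and human, with points for replicates and lines for the mean of 2. Mouse H3K4me3 lay at 31.5 and 30.4 Mb in naive cells and at 38.7 Mb or more at every Th9 stage, while human naive replicate 1 lay at 62.9 Mb for H3K4me3 against 42.7 Mb in replicate 2.

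Il9, the cytokine gene that defines the subset (mouse, mm10, 13:56479277-56482257), gained acetylation on activation and lost it after the stimulus ended. H3K27ac within the gene and 30 kb on each side covered 5146 ± 814 bp in naive cells, 13434 ± 349 bp at day 3, 7138 ± 3816 bp at day 4 and 1675 ± 798 bp at day 8. The change from naive to day 3 was 1.33 on the log2 scale (SE 0.44, limma adjusted p = 0.033). The change from day 3 to day 8 was -3.25 (SE 0.44, adjusted p = 6.6e-04). H3K4me1 in the same window rose by 0.54 by day 3 (adjusted p = 0.026) and was lower by day 8 than at day 3 (-0.62, adjusted p = 0.019). H3K4me3 at the ends of Il9 covered no bp in naive cells, 5655 and 5983 bp in the day 3 libraries, and 726 and 1151 bp at day 8. The day 3 to day 8 difference did not pass (adjusted p = 0.24). A region over the gene, 13:56476204-56483610, carried H3K27ac in both libraries of naive cells, day 3 and day 4 and in neither at day 8. Regions at 13:56487832-56489321, 5575 bp from the gene, and 13:56501678-56504206, 19421 bp away, carried it in both day 3 libraries and in neither naive nor day 8 library. A region 22396 bp away, 13:56504653-56509468, carried it in both libraries of all 4 stages. The window also takes in part of the neighbouring gene Slc25a48. The rise from naive to day 3 was a weak call: its adjusted p was 0.153 without naive replicate 1, 0.0776 without naive replicate 2, 0.0741 without day 3 replicate 1 and 0.133 without day 3 replicate 2. It was 0.319 with equal covered length (log2 change 1.56) and 0.288 with a stricter score (log2 change 1.55). It was 0.139 with no filter, 0.0504 with a pseudocount of 50 bp and 0.0553 with plain eBayes. Over all alternatives it ran from 0.00161 to 0.319.

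**Figure D2:**
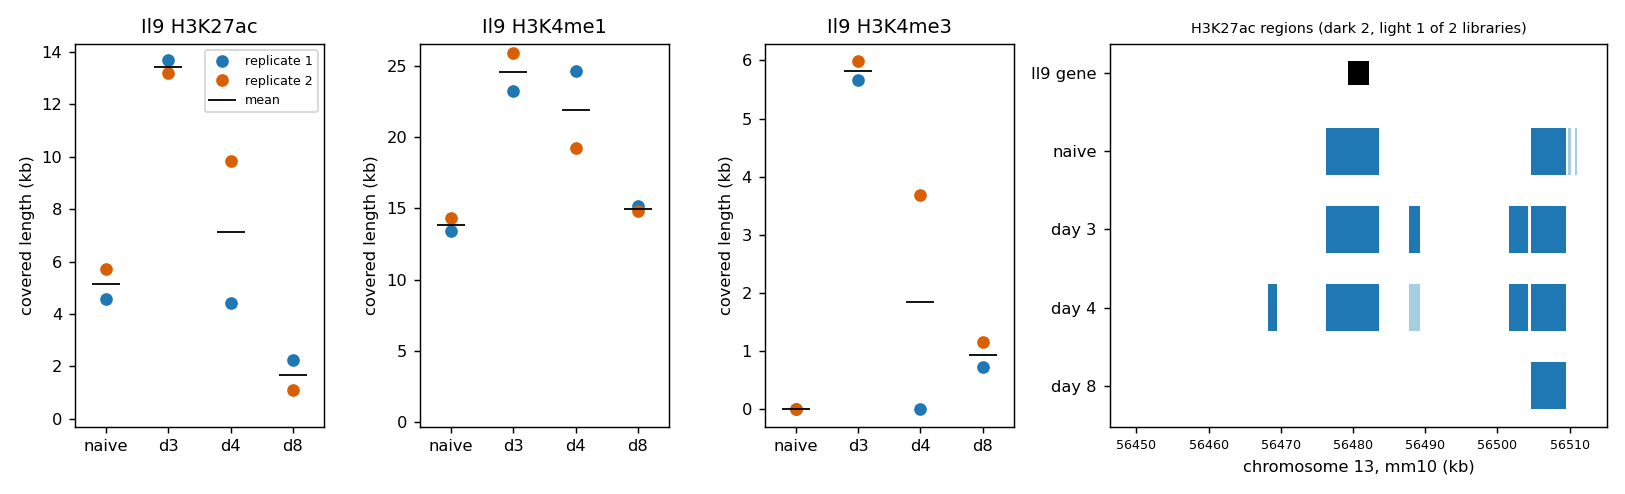
Covered length of the 3 marks in the Il9 window (kilobases, vertical axis) by stage, with points for replicates and lines for the mean of 2, and a map of H3K27ac regions on mouse chromosome 13 (horizontal axis, position in mm10 in kb; dark bars in both libraries, light bars in 1). The H3K27ac region over the gene, present in naive, day 3 and day 4 libraries, is missing at day 8.

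The comparison of mouse day 3 with naive cells set the marks before and after the first days of stimulation with polarizing cytokines side by side. No culture with the stimulus or the cytokines alone is among the samples. Effects of the stimulus, the cytokines and time in culture can therefore not be told apart. H3K27ac rose at 12 of 14 Th2 genes, with 1 fall, and fell at 17 of 20 naive and resting T cell genes, with 0 rises (limma and camera, adjusted p = 3.4e-05 and 1.2e-05). Neither list call held with an estimated correlation (adjusted p = 0.132 for the Th2 and adjusted p = 0.305 for the naive and resting genes). Il4, the signature Th2 cytokine gene, went from 2543 ± 335 to 21908 ± 4753 bp (log2 change 2.97, SE 0.13). Il13 went from 1590 ± 486 to 28780 ± 5461 bp (4.00, SE 0.18), and the anti-inflammatory cytokine gene Il10, of the Th9 cytokine and receptor list, from 1830 ± 445 to 24760 ± 2539 bp (3.61, SE 0.15). Among the naive and resting genes Tcf7, a factor of naive and memory cells, went from 72640 ± 1415 to 29392 ± 4902 bp (-1.34). Of 16957 gene windows tested with limma, 4561 were longer covered and 4678 shorter at day 3, and 2281 and 1934 of these changed by at least 1 on the log2 scale. Genes whose windows share peaks moved together, as did Il4, Il13 and Rad50, or Il10, Il19, Il20 and Il24.

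Several of the largest rises started from no H3K27ac in either naive library. The glutamate transporter gene Slc1a2 (2:102658239-102790784) was listed at 0 in naive cells and at 59608 ± 8349 bp at day 3. Timd2, a ferritin receptor gene, reached 29406 ± 3020 bp and Rgs13, a regulator of G protein signalling, 22038 ± 21.9 bp, both from 0. The most changed peaks of the Rgs13 window lay 20063 bp from the gene. Kcnk10, a potassium channel gene, went from 0 to 20996 ± 1525 bp, and Il20 with its neighbour Il19 went from 0 to 16860 ± 5553 bp. The Il17f window, shared with Il17a and holding cytokines of Th17 cells, went from 0 to 15551 ± 813 bp. Ang5 (with Ang6 and Ear10) went from 0 to 23968 ± 5791 bp, Twist2 from 0 to 15306 ± 3913 bp and BC053393 (with Dppa1) from 0 to 11328 ± 4007 bp. Psmb7, placed here by its neighbour Nek6 with the larger change, went from 1532 ± 28.3 to 39818 ± 13973 bp (4.46). Among the largest falls were genes named for interferon induction: Ifi206, placed by its neighbour Ifi214, went from 27958 ± 2710 to 3240 ± 624 bp (-3.07) and Ifi213 (with Ifi209) from 17390 ± 1368 bp to 0. Ly6c1, a surface antigen of memory and myeloid cells, went from 23556 ± 445 bp to 0, and Camk1g (with Lamb3) from 18220 ± 2952 to 210 ± 297 bp (-5.73). Dmbt1, Khdrbs3, Kcnc1 (with Myod1), Rtp4 (with Masp1), Adam6b and Urad (with Cdx2) went to 0 from between 10095 and 12256 bp.

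Of 17 gene lists, 6 passed a camera test with a preset correlation of 0.01 at day 3, and in each list the counts adjusted over the list alone equalled those over all genes tested. The 17 falls of naive and resting T cell genes also included Foxo1 (-1.32), S1pr1, the exit receptor of lymph nodes (-1.18), and Satb1 (-1.38), and the 12 rises of Th2 genes the chemokine receptor gene Ccr4 (1.94) and Maf (1.29). The 1 fall of a Th2 gene was lost without centring, with scaling to the total, narrower windows, no filter or plain eBayes, and without any of the naive or day 3 libraries (11 and 0 without naive replicate 1 or day 3 replicate 1, 10 and 0 without naive replicate 2 or day 3 replicate 2). Of 12 Th17 genes 9 rose and 3 fell (adjusted p = 6.9e-04, adjusted p = 0.132 with an estimated correlation), led by Rora (1.82), Ccr6 (3.24) and Ahr (2.36). The 3 falls became 0 without naive replicate 1 or with equal covered length and 1 without naive replicate 2 or without centring. Of 25 activation genes 16 rose and 2 fell (adjusted p = 0.0020, adjusted p = 0.305 with an estimated correlation), including Egr2 (1.46), the T cell growth factor gene Il2 (1.18), the glucose transporter gene Slc2a1 (1.13) and the amino acid transporter gene Slc7a5 (1.78). The 2 falls became 1 without day 3 replicate 1, naive replicate 1 or any of the day 4 and day 8 libraries, and 1 or 0 in most other settings. Of 13 regulatory T cell genes 8 rose and 0 fell (adjusted p = 0.0058, adjusted p = 0.354 with an estimated correlation), with the IL-2 receptor gene Il2ra at 1.33 and Ctla4 at 0.82. Of 20 Th9 cytokine and receptor genes 12 rose and 5 fell (adjusted p = 0.0058, adjusted p = 0.152 with an estimated correlation), with the chemokine genes Ccl17 at 1.87 and Ccl20 from 0 to 13336 ± 5140 bp. The falls numbered 3 without naive replicate 1 or day 3 replicate 1, without centring, with equal covered length or with narrower windows. No call of a list held with an estimated correlation. That test also has far fewer degrees of freedom, so these losses do not show correlation between the genes of a list.

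The list of Th9 transcription regulators did not pass (12 of 24 rose, 5 fell, adjusted p = 0.0727), though single members moved far. Batf3, a factor of activated T cells and dendritic cells, rose by 4.26 on the log2 scale, the lipid sensor gene Pparg by 6.03 from 126 ± 177 bp, Nfkb1 by 1.80 and Batf by 1.56. Irf1, an interferon-induced factor, fell from 38094 ± 1708 to 5454 ± 660 bp (-2.79) and Smad3 had a log2 change of -1.01. Cell cycle genes (8 rose, 3 fell of 19, with Mcm3 at 2.02) and cytokine signalling inhibitors and STAT targets (6 rose, 4 fell of 16, with Socs2 at 2.45 and Cish at 1.15) did not pass, at adjusted p = 0.227 and 0.476. Without naive replicate 2 or day 3 replicate 1, 5 cell cycle genes rose, and without naive replicate 1 the count was 6 rising and 1 falling. The STAT list had 5 rising and 2 falling without naive replicate 1 or day 3 replicate 1. Of 8 follicular helper genes 2 rose and 3 fell (adjusted p = 0.643), Cxcr5 at -1.35. There was 1 fall without naive replicate 1 or day 3 replicate 1, and no excess of falls without centring (2 and 2) or with scaling to the total (2 and 1).

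Markers of other cell types and control genes moved both ways at day 3, and none of their lists passed. Of 15 Th1 and cytotoxic genes 1 rose and 6 fell (adjusted p = 0.257), Prf1, the pore protein of killer cells, going from 15890 ± 4923 to 1407 ± 358 bp (-3.33) and the chemokine receptor gene Cxcr3 rising by 2.54. Without naive replicate 2 the count was 5 rising and 6 falling. Of 10 NK and CD8 T cell genes 1 rose and 4 fell (adjusted p = 0.293), Cd8b1 at -1.78 and Xcl1 at -1.20. The count was 1 and 7 without naive replicate 1, 2 and 3 without naive replicate 2 or day 4 replicate 2, and 2 and 4 without day 4 replicate 1. In these lists the naive libraries differed beforehand: replicate 2 was longer covered than replicate 1 at 14 of 15 Th1 and cytotoxic genes. B cell genes had 2 rises and 3 falls of 11 (Ebf1 at 2.32, Cd79a at -0.85; adjusted p = 0.548), and myeloid genes 2 and 4 of 10 (Itgam at -2.34, Csf1r from 0 to 2784 ± 771 bp; adjusted p = 0.606). There was 1 myeloid rise without either day 3 library (1 and 3 without replicate 1, 1 and 4 without replicate 2). Erythroid and platelet genes had 2 rises, both of the shared Pf4 and Ppbp window, and 1 fall of 9 (adjusted p = 0.986). It had 2 falls without day 3 replicate 1, 0 rises without day 3 replicate 2 and 0 falls without naive replicate 2. Housekeeping genes had 5 rises and 4 falls of 15 (Cltc at 0.84, Rpl13a at -0.87; adjusted p = 0.986), turning to 3 and 4 without centring. They had 3 and 3 without day 3 replicate 1 or either naive library, and 2 and 4 without day 3 replicate 2. Genes silent in T cells had 4 rises and 2 falls of 14 (Tnnt2 at 1.66, Myod1, in the Kcnc1 window, from 11032 ± 316 bp to 0; adjusted p = 0.986). In the housekeeping and silent lists camera's direction and the median differed in sign (median 0.04 with camera down, and -0.03 with camera up).

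**Figure D3:**
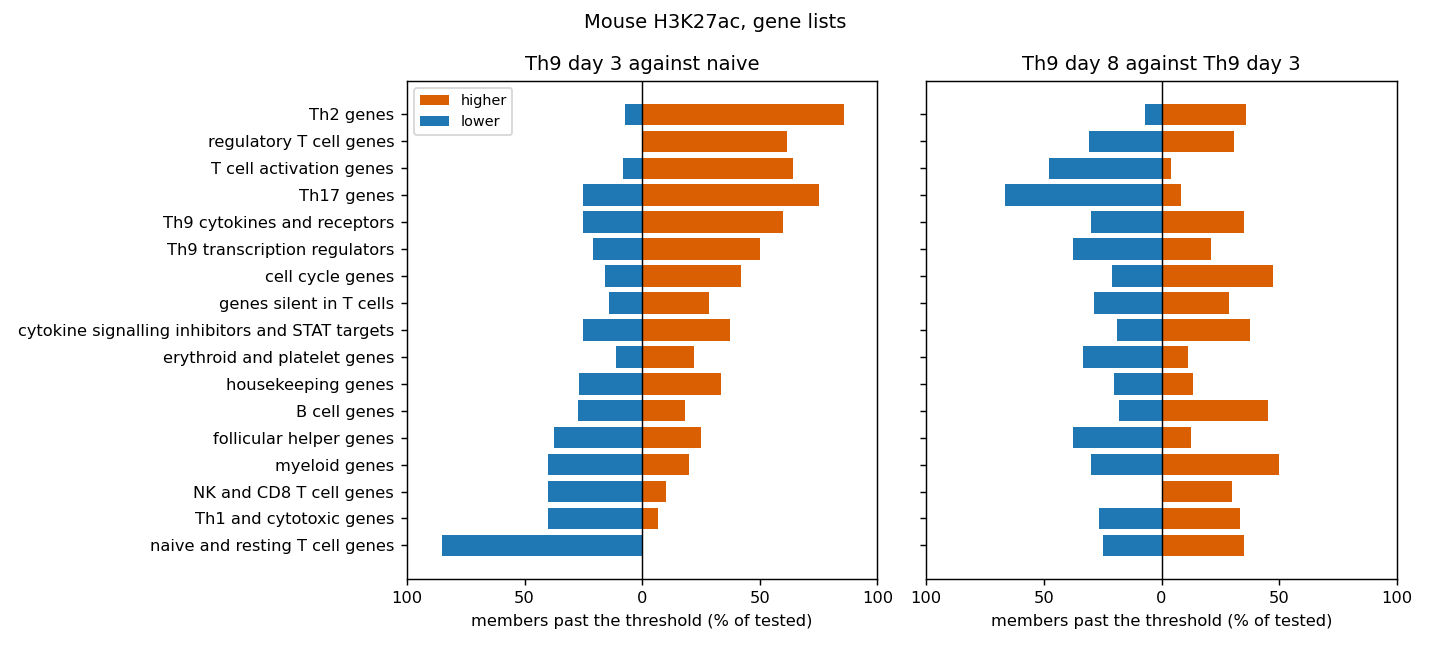
Members of each of the 17 lists past the threshold for mouse H3K27ac (horizontal axis, percent of the members tested), longer covered to the right and shorter to the left, for day 3 against naive and day 8 against day 3. Naive and resting genes are all to the left at day 3 (17 of 20), and activation genes go from 16 rises and 2 falls to 1 rise and 12 falls.

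The H3K4 marks also moved at day 3 at several of the lists. H3K4me1 rose at 12 of 12 Th17 genes (adjusted p = 1.1e-06, adjusted p = 0.54 with an estimated correlation), Il17f going from 0 to 28090 bp, and at 15 of 20 Th9 cytokine and receptor genes with 2 falls (adjusted p = 1.8e-05, adjusted p = 0.54 with an estimated correlation), Il10 at 3.05. It rose at 11 of 14 Th2 genes (adjusted p = 4.3e-05, adjusted p = 0.54 with an estimated correlation) and 7 of 13 regulatory T cell genes (8 adjusted over the list alone; adjusted p = 0.0032, adjusted p = 0.54 with an estimated correlation), with 0 and 1 falls. It rose at 13 and fell at 2 of 25 activation genes (adjusted p = 0.015, adjusted p = 0.60 with an estimated correlation) and fell at 12 of 20 naive and resting genes (adjusted p = 0.0032, adjusted p = 0.60 with an estimated correlation). H3K4me3 appeared at Il2ra (0 to 4906 ± 132 bp), the regulatory T cell factor Foxp3 (0 to 3418 ± 80 bp) and Il4 (0 to 1211 ± 120 bp). It rose at 15 of 19 cell cycle genes (16 adjusted over the list alone; adjusted p = 6e-06, adjusted p = 0.20 with an estimated correlation), such as Pcna (3800 to 7956 bp) and Mcm5 (1898 to 3772 bp). Its count of 16 falls among 20 naive and resting genes owed much to centring, since 8 of them had fewer covered bp in both day 3 libraries. In all, 4362 windows gained and 4959 lost H3K4me1 of 17897, or 2978 and 633 without centring, which raised each log2 change by 0.28, and the falls numbered 3183 without naive replicate 2 and 3250 without day 3 replicate 1. Another 2423 gained and 3273 lost H3K4me3 of 13954, or 9716 and 217 without centring, a shift of 0.43. Of the 3273 lower H3K4me3 calls 2608 were not lower in covered bp, so these falls are relative to a general lengthening. The total of 5696 was 3720 without day 3 replicate 1 and 3569 without day 3 replicate 2.

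From day 3 to day 8, after the receptor stimulus was withdrawn, 12 of 25 activation genes and 8 of 12 Th17 genes lost acetylation relative to the median window, and 1 of each list rose. The list calls (adjusted p = 0.0080 and 0.032) were lost with an estimated correlation (adjusted p = 0.622 for both). Of the falls 10 and 6 had fewer covered bp in both day 8 libraries than in either day 3 library. Without centring, a shift of 0.32, the falls numbered 6 and 3, with equal covered length 7 and 5, and Th17 falls 5 with a stricter score. Egr2 went from 30722 ± 3645 to 9619 ± 711 bp (-1.98), Il2 from 15032 ± 193 to 6708 ± 747 bp (-1.47) and the early response gene Nr4a2 from 8511 ± 849 to 4928 ± 327 bp (-1.09), against a rise at the costimulator gene Icos (0.86). The Th17 falls included Ahr (-1.02) and Il23r (-1.71). There were 0 Th17 rises with scaling to the total, no filter or plain eBayes, and without either day 3 library, either naive library or day 8 replicate 1 (8, 6, 9, 9 and 7 falls without day 3 replicates 1 and 2, naive replicates 1 and 2 and day 8 replicate 1). Among lists that did not pass, single genes moved both ways: Mki67, a marker of dividing cells, went from 5854 ± 92 to 31166 ± 1797 bp (2.05), Irf1 from 5454 ± 660 to 25626 ± 861 bp (1.87) and Tcf7 from 29392 ± 4902 to 62935 ± 956 bp (0.78), while the resting cell factor gene Foxp1 was at -1.37. Over all windows 4205 rose and 4094 fell (1882 and 1410 by at least 1 on the log2 scale), and without centring 5621 rose and 1579 fell.

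Most of the largest day 8 rises and falls were again windows empty or nearly so at 1 of the stages. Kcnc1 with Myod1 went from 0 at day 3 to 24135 ± 991 bp and the glutamate receptor gene Grik2 from 0 to 17108 ± 4074 bp. The chemokine receptor gene Ccr1l1 went from 0 to 14426 ± 3867 bp, Mrln from 0 to 13323 ± 1919 bp, Atp6v0a4, a proton pump subunit gene, from 247 ± 349 to 27266 ± 817 bp (5.88) and Cog7 from 1493 ± 8.49 to 15422 ± 476 bp (2.88), placed here by its neighbour Scnn1b with the larger change. The olfactory receptor gene windows Olfr157 and Olfr1410 and Camk1g rose as well. Ccr3, the eotaxin receptor gene, went from 0 to 13126 ± 2596 bp, a call lost with equal covered length (adjusted p = 0.971) and with a stricter score (0.343). Ccl20 (with Daw1) fell from 13336 ± 5140 bp to 0 and Idi2 (with Gtpbp4) from 11560 ± 1665 bp to 0. Fem1al fell from 8810 ± 330 bp to 0 and F13a1, coagulation factor XIII, from 17786 ± 484 to 192 ± 271 bp (-6.04). The most changed peaks lay 16496 bp from Ccl20, 20059 bp from Fem1al and 24296 bp from Ccr1l1, so these are changes of windows. Adgrg6, Gm30733, the chromatin protein gene Hmga2, the linker histone gene H1f10 and Prmt8 went to 0 from between 4736 and 7940 bp, and Il9 (-3.25) stood among the 10 largest falls by its neighbour Slc25a48, with which it was counted.

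No other list passed at day 8, and the counts of several turned with the centring. Naive and resting genes had 7 rises and 5 falls of 20 (11 and 2 without centring; adjusted p = 0.855), S1pr1 at 0.96 and Il7r at 0.67 against Btla at -1.54. Th9 transcription regulators had 5 rises and 9 falls of 24, turning to 8 and 1 without centring (Hif1a at 0.80, Erg at -3.78). The count was 3 and 7, 4 and 4, and 3 and 4 without day 3 replicate 1, day 3 replicate 2 and day 8 replicate 1. Th9 cytokine and receptor genes had 7 rises and 6 falls of 20, turning to 5 and 7 with scaling to the total (Il3 at -1.70, Ccl17 at -1.23), with 3 and 5 without day 3 replicate 2 and 2 and 5 without day 8 replicate 1. Cell cycle genes had 9 and 4 of 19 (11 and 4 adjusted over the list alone; Top2a at 1.04; adjusted p = 0.18), with 8 and 1 without day 3 replicate 2 and 8 and 2 without day 8 replicate 2. Th2 genes had 5 rises and 1 fall of 14 (3 and 1 adjusted over the list alone, 3 and 3 with scaling to the total), Maf at 0.93. There were 3 rises without day 3 replicate 1 or 2 or day 4 replicate 1 or 2 and 2 without day 8 replicate 1. Regulatory T cell genes had 4 rises and 4 falls of 13 (5 and 1 without centring; Itgae at 1.05, Ikzf2 at -1.58), and 3 and 2 without either day 3 library and 3 and 1 without either day 8 library. Follicular helper genes had 1 and 3 of 8 (Tox at -1.83). STAT targets had 6 and 3 of 16 (Bcl2l11 at 1.09, Dusp4 at -0.81), with 5 and 5 without day 3 replicate 1 and 3 and 3 without day 3 replicate 2 or day 8 replicate 1.

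Of the lists for other cells, Th1 and cytotoxic genes had 5 rises and 4 falls of 15 at day 8 (Stat4 at 0.82), with 1 fall without day 3 replicate 1 or either day 8 library (4, 4 and 5 rises). NK and CD8 T cell genes had 3 rises and 0 falls of 10 (Gzmk at 1.30). B cell genes had 5 and 2 of 11 (Cd22 at 2.79, Ebf1 at -2.50), with 2 and 2 without day 8 replicate 1. Myeloid genes had 5 and 3 of 10 (Mpeg1 at 1.08), with 3 and 2, 3 and 1, and 2 and 2 without day 3 replicate 1, day 3 replicate 2 and day 8 replicate 1. Erythroid and platelet genes had 1 and 3 of 9, turning to 3 and 2 without centring, with 0 rises without day 3 replicate 2 or day 8 replicate 1 and 2 without day 8 replicate 2. Housekeeping genes had 2 and 3 of 15, turning to 4 and 1 without centring (Rpl13a at 0.90, Cltc at -1.05), and genes silent in T cells 4 and 4 of 14, with 2 rises without day 8 replicate 2. Adjusted over the list alone the counts of these 7 lists were the same, and their adjusted p lay between 0.734 and 0.936.

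The step from day 3 to day 4 held 1689 rises and 1618 falls of H3K27ac and the step from day 4 to day 8 3133 and 2643, or 4639 and 768 without centring. The earlier step held 1084 and 751, 977 and 851, and 772 and 1002 without day 3 replicate 1, day 3 replicate 2 and day 4 replicate 1. The later step held 2072 and 1657, 1884 and 1666, and 2049 and 1809 without day 4 replicate 2, day 8 replicate 1 and day 8 replicate 2. At day 8 activation genes also had fewer H3K4me3 bases, such as Egr2 (7652 at day 3 to 2016 bp) and Il2 (3242 bp to 0), with 9 falls and 4 rises of 22 genes (adjusted p = 0.0084, adjusted p = 0.86 with an estimated correlation). Naive and resting genes had 13 rises and 1 fall (14 and 1 adjusted over the list alone; adjusted p = 0.0092, adjusted p = 0.86 with an estimated correlation), 6 of the rises with more bp in both day 8 libraries. H3K4me1 fell at Ccl20 (21658 to 1790 bp) and Il2 (-1.17), and no list passed. H3K4me1 windows counted 3439 rises and 3073 falls (547 and 836 without centring), and their total of 6512 was 3624, 3741, 3629 and 3995 without day 3 replicates 1 and 2 and day 8 replicates 1 and 2. H3K4me3 windows counted 1887 rises and 1021 falls, turning to 462 and 3786 without centring, a shift of -0.22, and to 492 and 867 with scaling to the total. Their total of 2908 was 740, 992, 1167 and 978 without day 3 replicates 1 and 2 and day 8 replicates 1 and 2.

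Regions acetylated on activation mostly acquired H3K4me1 with it. In mouse 8781 merged regions carried H3K27ac in both day 3 libraries and neither naive library, 6808 the reverse, and 19380 were kept. The counts were 5082 and 2200 with equal covered length, and with a peak required to cover 50% of a region losses were more frequent (7812 and 8944). Dividing the same 4 libraries by replicate number gave 223 and 60 regions and the crossed division 31 and 185. Of the 8781 gained regions 85.8% lay at least 2.5 kb from a gene end, 23.7% had H3K4me1 in both naive libraries (37.2% with a stricter score) and 97.7% in both day 3 libraries. H3K27ac was still in both libraries at 56.8% of them on day 4 and 36.9% on day 8, and H3K4me1 at 75.4% and 61.7%, and 14.7% had H3K4me1 with no H3K27ac on day 8. With a stricter score H3K4me1 was at 51.8% of gained regions on day 4 and 63.3% on day 8. Kept regions then also stood lower on day 4, at 35.8% against 91.4% on day 8. Only 11699 H3K4me1 peaks of day 4 replicate 2 passed this score, against 37988 of replicate 1. This turn is therefore not particular to gained regions and may reflect that library. Of the 6808 lost regions 96.4% had H3K4me1 in naive cells and 52.8% at day 3 (10.5% with equal covered length). H3K27ac was back in both libraries at 12.1% on day 4 (5.05% with a cover of 50%) and 50.1% on day 8. With equal covered length H3K27ac was on 14.3% and H3K4me1 on 33.2% of gained regions and H3K27ac back on 16.3% of lost regions at day 8. From day 3 to day 8 a further 9700 regions were gained and 4888 lost, and with equal covered length the direction turned, to 766 gained and 5367 lost. The trimming kept day 3 replicate 2 whole, with −log10 q down to 2.02, and cut the day 8 lists at 29.1 and 18.6. This alone can make weak day 3 regions count as lost, so the turn does not show a loss.

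**Figure D4:**
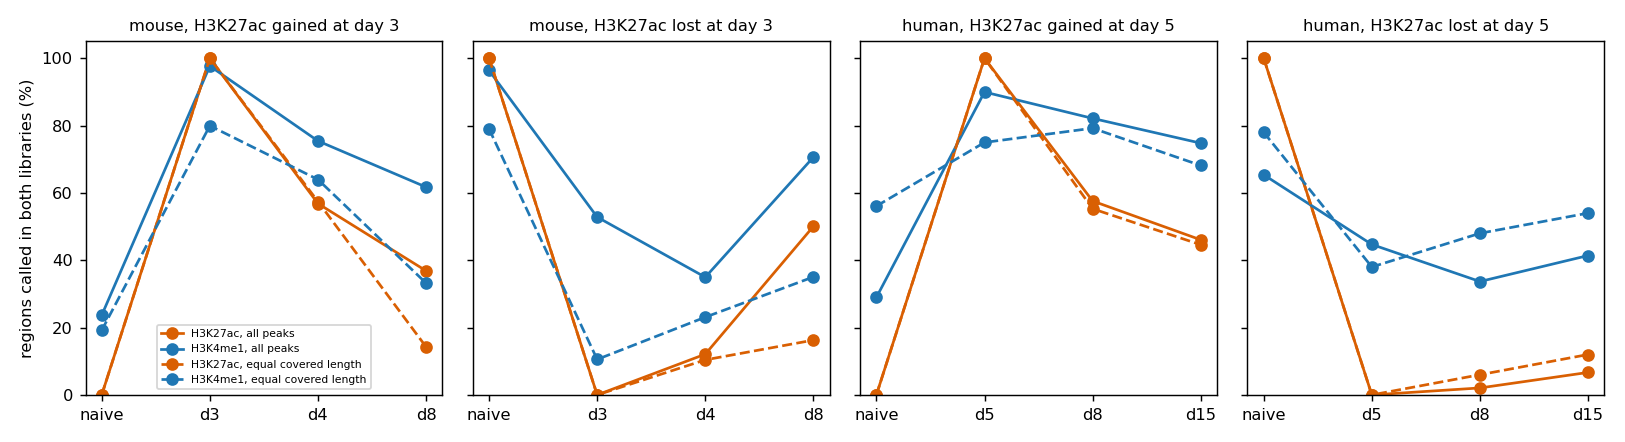
Share of regions (percent, vertical axis) carrying H3K27ac or H3K4me1 in both libraries at each stage, for regions that gained or lost H3K27ac at the first Th9 stage in mouse and human, with all peaks (solid lines) and with equal covered length (dashed lines). In mouse gained regions H3K4me1 stays at 61.7% at day 8 while H3K27ac is at 36.9%, and in lost regions H3K27ac returns to 50.1%, or to 16.3% with equal covered length.

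Human naive cells also gained many acetylated regions by day 5 of culture. With no human gene table used here, windows were tiles of 60 kb on hg38, and human IL9 was not analysed here. H3K27ac rose in the tile 16:11160001-11220000 from 0 to 38224 ± 11308 bp and was at 12000 ± 1208 bp by day 15, in 10:30720001-30780000 from 0 to 20754 ± 4212 bp, and in 1:93600001-93660000 from 0 to 16932 ± 4516 bp. It fell in 5:66000001-66060000 from 8364 ± 762 bp to 0, in 3:101340001-101400000 from 4754 ± 921 bp to 0, and in 21:15780001-15840000 from 7224 ± 2650 to 87 ± 123 bp (-4.74). These 3 falling tiles were covered in too few libraries to be tested with equal covered length or a stricter score. Of 19577 tiles 2716 rose and 1804 fell with limma, or 1055 and 127 without centring, and 5121 merged regions were gained, 1063 lost and 20136 kept. The rises numbered 1612 and the falls 560 without naive replicate 1, 1703 and 710 without naive replicate 2. Dividing the 4 libraries by replicate number gave 3223 regions found in both replicate 1 libraries and in neither other, more than the regions lost. Gained and lost regions numbered 3406 and 50 with equal covered length and 1446 and 252 with a stricter score. The trimming to equal length kept day 5 replicate 2 whole, with −log10 q down to 2.00, and cut the naive lists at 27.9 and 8.83. This alone can leave few regions to count as lost, so the 50 do not show that losses were rare. Of the gained regions 29.0% had H3K4me1 in both naive libraries (56.1% with equal covered length, 17.4% with a stricter score), against 82.1% at day 8 and 74.8% at day 15. For H3K4me1 the trimming kept naive replicate 2 whole, which can raise the 56.1%.

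After the stimulus ended, human cells gained H3K27ac from day 5 to day 15 in 9:3840001-3900000 (0 to 9248 ± 3570 bp) and 1:70740001-70800000 (0 to 8386 ± 950 bp) and lost it in 22:49980001-50040000 (10150 ± 3963 bp to 0) and 17:56580001-56640000 (11085 ± 2988 to 154 ± 218 bp, -4.96). By limma the rise in 9:3840001 (log2 change 5.67) was lost with equal covered length (2.14, adjusted p = 0.595) and a stricter score (4.08, adjusted p = 0.108). That in 1:70740001 (5.58) was lost with equal covered length, though the change was about as large (5.31, limma adjusted p = 0.0634). With a stricter score the fall in 22:49980001 went from -5.48 to -4.13 (limma adjusted p = 0.112). The fall in 17:56580001 was then at -3.04 (limma adjusted p = 0.349). Of the 5121 regions gained by day 5, 57.6% had H3K27ac in both libraries on day 8 and 46.1% on day 15, while H3K27ac was back on 2.07% and 6.68% of the 1063 lost regions (5.16% and 17.1% with a stricter score, 6% and 12% with equal covered length). From day 5 to day 15 limma called 1385 tiles higher and 1593 lower, but 8 and 5 without centring, a shift of -0.16. Rises numbered 190 without day 15 replicate 1 and 284 without day 15 replicate 2, and falls 932 without day 5 replicate 1, 329 without day 15 replicate 1 and 505 without day 15 replicate 2. The step from day 5 to day 8 held 340 rises and 408 falls (150 and 198 with the replicate as a block), and leaving out any of the 8 libraries moved this count, to between 0 by limma without day 8 replicate 2 (2976 tiles at unadjusted p under 0.05) and 1127 without day 5 replicate 1. The step from day 8 to day 15 held 0 rises and 2 falls by limma (1826 tiles at unadjusted p under 0.05), in 22:49980001-50040000 and in 1:23400001-23460000 (2878 ± 388 bp to 0), named after their values were seen.

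H3K4me1 was gained in 16178 human regions and lost in 1035 by day 5, while 3946 followed the division by replicate number. Region counts were 4640 gained and 3481 lost with equal covered length, and with a stricter score 7890 and 156. Of 26048 tiles 5919 rose and 3481 fell. These were 5529 and 168 without centring, a shift of 0.42, and 4314 and 2074 without day 5 replicate 2. H3K4me3 had 708 regions gained and 1066 lost, fewer than the 2517 that followed the division by replicate number, and the direction turned with a stricter score (103 and 15) and with equal covered length (281 and 79). Of 37840 tiles 1674 were higher and 1946 lower. These tile counts were 1584 and 344, 1032 and 609, 1062 and 2600, and 1009 and 1298 without naive replicates 1 and 2 and day 5 replicates 1 and 2. From day 5 to day 15 H3K4me1 rose in 880 tiles and fell in 1535 (33 and 166 without centring). Their total of 2415 was 1395, 153, 455 and 574 without day 5 replicates 1 and 2 and day 15 replicates 1 and 2. H3K4me3 rose in 247 and fell in 557. Their total of 804 was 290 with the replicate as a block, 7 without day 5 replicate 2, 60 without day 15 replicate 1 and 272, 289, 484, 494 and 506 without day 15 replicate 2, day 5 replicate 1, naive replicate 2, day 8 replicate 1 and day 8 replicate 2.

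The extent of each mark was compared between naive and all Th9 libraries with 2-sided exact permutation tests over the 28 divisions of 8 libraries into 2 and 6. Mouse H3K4me3 covered 30.9 ± 0.794 Mb in naive (n = 2) and 43.1 ± 3.39 Mb in Th9 libraries (n = 6), p = 0.0357 by the exact test, the smallest that it allows, and 0.241 after Benjamini-Hochberg adjustment over 18 tests. Human H3K4me1 peaks numbered 52114.5 in naive and 71918 in Th9 libraries, with the same exact p, and human H3K4me3 covered 52.8 ± 14.3 and 46.0 ± 4.03 Mb. No test passed after adjustment. The divisions ignored the replicate numbers, which may pair the mouse H3K4me3 libraries. Only 16 of them set apart 1 library of each number, too few for a p under 0.05. In mouse 2883 H3K27ac regions were in all 6 Th9 libraries and neither naive one and 2277 the reverse, and in human 2181 and 854. The corresponding counts were 5169 and 2735 for mouse H3K4me1, 1321 and 239 for mouse H3K4me3, 7244 and 857 for human H3K4me1 and 258 and 908 for human H3K4me3. For human H3K4me3 another division, naive and day 5 replicate 1 against the rest, separated 1570 regions, more than the 1166 between naive and Th9 libraries. With equal covered length the counts were 709 and 1351 for mouse H3K27ac, 1237 and 1314 for mouse H3K4me1 and 10 and 3127 for mouse H3K4me3, all with more regions on the naive side. For mouse H3K4me3 the trimming kept naive replicate 2 whole and cut every Th9 list at a −log10 q of 49.6 or above, which favours naive regions. In human the counts with equal covered length were 1422 and 24 for H3K27ac, 1785 and 1771 for H3K4me1 and 110 and 46 for H3K4me3. For human H3K27ac the trimming kept day 5 replicate 2 whole and cut the naive lists at a −log10 q of 27.9 and 8.83, which favours Th9 regions. A cover of 50% also turned mouse H3K27ac (1589 and 3937), mouse H3K4me1 (3104 and 4726) and human H3K27ac (1086 and 2298), and a stricter score mouse H3K4me1 (1374 and 1840) and human H3K4me3 (50 and 12).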

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

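The tests weighed here were chosen after the results they bear on were seen, except the tests on the highest-scored lost regions and on H3K4me1 and H3K4me3 at cytotoxic genes, which were chosen before; the comparison of the highest-scored regions with all lost regions came after.

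H3K4me3 was higher in Th9 than in naive cells in mouse and lower in human, but the difference between the species did not pass adjustment. The difference in mean log2 number of peaks, Th9 minus naive, was 0.25 in mouse and -0.32 in human, a difference of 0.57 (exact permutation over 784 pairs of splits, p = 0.0204, 0.0612 after Benjamini-Hochberg adjustment over 6). For covered length it was 0.47 in mouse and -0.18 in human, a difference of 0.65 (exact permutation p = 0.00893, adjusted 0.0536). Both tests ignored the replicate numbers, which may pair the libraries. With a stricter score the difference in covered length was still 0.58, nearly all of it the mouse rise (0.577). This argues against weak peaks near the calling threshold as the whole cause of that rise, though a deeper library passes this score more easily. The human change was then 0.0017, so weak peaks may account for the human fall. Human naive replicate 1, with 62.9 Mb against 42.7 Mb in its partner, may account for the human direction: without it the human change was 0.10, above 0, and the gap to mouse 0.37 (exact permutation over 196 pairs, p = 0.117), or 0.25 for the number of peaks (exact permutation p = 0.24), which was 0.90 without human naive replicate 2. What stays open is the biology of the species, which was not tested, and the cultures, which differed in length and in cytokines.

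Mouse regions that lost H3K27ac by day 3 carried it again in both day 8 libraries at 50.1% of 6808, against 12.1% in both day 4 libraries. More peaks were called at day 8, and with equal covered length the shares were 16.3% and 10.4%, so longer lists could account for part of the difference, and whether for all of it stays open. Peaks missed at day 3 might also be called again, yet the share at day 4 was 0.242 of that at day 8; with equal covered length this ratio was 0.640, which leaves that open too. For cells that stayed naive in culture, the bound set beforehand was at most 5% of the highest-scored lost regions in neither day 8 library. Of the 681 lost regions in the top 10% by naive score 9.25% (95% exact interval 7.18 to 11.7) were in neither, above the bound. Yet signal from a minority of naive cells could stay under the peak threshold at some regions, so the bound cannot decide this. Of these 681 regions 82.4% were in both day 8 libraries, against 50.1% of all lost regions. A higher share among strong regions could come from any explanation given here, so it decides nothing. Cells that stayed naive are thus left open as a cause. A biological return of acetylation after the stimulus stays open as untested.

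In mouse naive cells, isolated by surface markers, replicate 2 had longer H3K27ac than replicate 1 at Th1 and cytotoxic genes, with a median log2 difference of 0.55 over 15 genes, the 100 percentile of 10000 random lists matched on covered length. Klrd1 covered 9432 bp in replicate 1 and 29898 bp in replicate 2, Ccl5 1308 and 10643 bp, Nkg7 5950 and 13362 bp and Tbx21 11492 and 19676 bp, and the NK and CD8 T cell list also stood at the 100 percentile (median 0.27, 8 of 10 genes longer in replicate 2), Cd8b1 (16693 and 7937 bp) and Cd8a (4947 and 2768 bp) being its 2 exceptions. A general lengthening of weakly covered windows in replicate 2 is argued against as the whole cause, since the highest median among those random lists was 0.18. Cytotoxic or memory-like lymphocytes in that preparation could be a source, although the isolation of naive cells is meant to remove them, but this cannot be told apart here: the 100 percentile only restates the pattern, and while H3K4me1 also stood at 100, the 48.1 of H3K4me3 decides nothing, with 7 of 11 members covered in a naive library and the median at the value of windows without peaks. The design gives no difference between these replicates, so no biological explanation was tested, and the genes of this list at day 3 should be read with that in mind.

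Whether the naive libraries separated from the Th9 libraries by more than other divisions of the same 8 was counted over 28 splits, which takes the 8 libraries as exchangeable. In mouse 5160 H3K27ac regions followed the real split and at most 3541 any other (the day 8 pair). In human 3035 followed the real split and at most 1915 any other. In both species 1 of 28 splits, the real one, reached the count with the lists as deposited. Yet the titles of each species carry 2 identifiers through all stages, and libraries of 1 stage had a higher median overlap, so the splits are not exchangeable. The splits that set apart 1 library of each identifier number 16, too few for a share under 0.05. The highest of the others among them held 3541 regions in mouse and 1214 in human. Chance can therefore not be excluded in either species. With equal covered length another of the 28 splits exceeded the real one in both species (2563 against 2060 in mouse, 2369 against 1446 in human). For human H3K4me3 2 of 28 splits reached the count of the real one, 4 with a stricter score and 6 with equal covered length.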

How the results depend on the processing

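The limit of at least 1 on the log2 scale, the interferon list, the counts of list members under every setting and the comparison of calls with raw covered bp were chosen after the results were seen, and the other alternatives were fixed beforehand.

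None of the 12 comparisons of peak number and covered length passed after adjustment, as reported, with a stricter score or with a library left out (96 comparisons), which in a design this small says nothing about stability. Of 192 limma counts under other settings 142 stayed within 1.5 times the reported count and 50 did not, and of 128 with a library left out 95 did and 33 did not. For named mouse genes 435 of 442 values kept their call and 7 lost it, and with a library left out 320 of 324 kept it and 4 lost it. Human tiles lost more calls: 329 of 376 values kept their call, 45 lost it and 2 reversed, and with a library left out 305 of 318 kept it and 13 lost it. In both species these counts leave out results whose window was covered in too few libraries to be tested. Of 41 mouse results 37 were tested with a stricter score, 37 with at least 4 libraries, and 39 without day 3 replicate 1 or 2. Of the human tiles tested, 13 of 40 lost their call without centring, 13 of 30 with equal covered length and 16 of 31 with a stricter score, and 1 reversed in each of the latter 2 settings. The 2 reversals, both of tile 16:74520001, were lost calls with a changed sign and values near 0, not calls in the other direction. Where no cause is given below, the cause was not tested. Since depth is unknown, a count that falls with equal covered length or a stricter score may reflect list length as well as cells, as for the human H3K27ac rises at day 5 (2716 reported, 1392 and 859). The stricter score drops the peaks with the lowest scores. Equal covered length does so in the longer lists only and keeps the shortest whole, here day 5 replicate 2.

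Requiring a change of at least 1 on the log2 scale, which by construction can only lower a count, left at mouse day 3 against naive 2281 higher and 1934 lower H3K27ac windows, 3571 H3K4me1 and 971 H3K4me3 windows. At day 8 against day 3 it left 1882 and 1410, 2214 and 332.

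Without centring mouse day 3 had 3611 H3K4me1 and 9933 H3K4me3 windows changed, and day 8 had 1579 lower H3K27ac and 1383 changed H3K4me1 windows. Human day 5 had 1055 higher and 127 lower H3K27ac tiles and 5697 H3K4me1 tiles. Human day 15 against day 5 had 8 and 5 H3K27ac, 199 H3K4me1 and 418 H3K4me3 tiles.

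With equal covered length mouse H3K4me1 had 4620 windows at day 3 and 3298 at day 8. Human day 5 had 1392 higher and 631 lower H3K27ac, 3648 H3K4me1 and 1241 H3K4me3 tiles, and day 15 had 398 and 306, 1313 and 186. Regions separating naive from Th9 libraries numbered 2060 in mouse and 1446 in human. In mouse 5082 regions were gained and 2200 lost by day 3 and 766 gained and 5367 lost from day 3 to day 8. In human 3406 were gained and 50 lost by day 5, and 735 gained and 1781 lost from day 5 to day 15. The trimming kept human day 5 replicate 2 whole, which can favour gains by day 5 and losses after it. At the last stage H3K27ac was on 14.3% and H3K4me1 on 33.2% of mouse gained regions and H3K27ac on 16.3% of lost ones, and in human on 44.6%, 68.1% and 12%.

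With a stricter score mouse H3K4me1 had 1710 windows at day 3 and 565 at day 8. Human day 5 had 859 higher and 470 lower H3K27ac, 2558 H3K4me1 and 793 H3K4me3 tiles. Human day 15 had 332 and 247 H3K27ac and 197 H3K4me3 tiles, and 0 H3K4me1 tiles by limma, with 1997 at unadjusted p under 0.05. Separating regions numbered 2317 and 985. Mouse steps held 3639 gained and 2813 lost, then 3631 and 2123. Human steps held 1446 gained and 252 lost, then 915 lost. At the last stage H3K4me1 was on 63.3% of mouse gained regions, and in human H3K27ac was on 58.7% and H3K4me1 on 81.1% of gained and H3K27ac on 17.1% of lost regions.

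With a peak required to cover 50% of a region, human regions lost by day 5 numbered 2957 and those gained from day 5 to day 15 2606. At the last stage H3K27ac was on 24.8% and H3K4me1 on 52.1% of mouse gained and H3K27ac on 39.4% of lost regions, and in human gained regions on 33.4% and 69.9%. Without a filter on covered windows mouse H3K4me3 had 13583 windows at day 3 and 11425 at day 8, because centring shifts windows at 0 bp in every library with almost no spread, and human H3K4me3 at day 15 had 445 tiles. Windows covered in at least 4 libraries gave 1640 human H3K4me3 tiles at day 5, and scaling to the total 1359 mouse H3K4me3 windows at day 8. Smaller tiles, of which more are tested, gave 4412 higher H3K27ac and 16063 H3K4me1 tiles at human day 5 and 5278 H3K4me1 tiles at day 15. With pseudocounts of 50 and 1000 bp human H3K4me1 at day 15 had 1469 and 3734 tiles.

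With an estimated correlation all 8 list calls were lost, at day 3 with camera adjusted p of 0.305 for activation, 0.132 for Th17, 0.132 for Th2, 0.152 for Th9 cytokine, 0.305 for naive and 0.354 for regulatory genes, and at day 8 with 0.622 for activation and 0.622 for Th17 genes. The fewer degrees of freedom of that test and the correlation between genes are not told apart in these losses. The human tile 16:74520001, which fell from 18108 ± 3826 to 1082 ± 1530 bp by day 5 (-4.75), had a log2 value of 0.028 with equal covered length and 0.14 with a stricter score.

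The replicate number as a block kept the counts of mouse H3K4me3 windows, the mark whose numbers may pair, within 1.5 times those reported at days 3 and 8. It moved human H3K4me3 at day 15 to 290 tiles from 804 and human H3K27ac from day 5 to day 8 to 150 higher and 198 lower tiles. It changed no other call of a list, named gene or tile, and no other reported count by over 1.5 times. Correlations of libraries with the same number lay from -0.019 to 0.222 in mouse H3K27ac, -0.088 to 0.090 in mouse H3K4me1, -0.114 to 0.270 in human H3K27ac, -0.056 to 0.296 in human H3K4me1 and -0.048 to 0.249 in human H3K4me3.

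Leaving out 1 library leaves a stage with a lone library, which is assumed to vary like the other groups. Mouse H3K4me3 then ranged from 3569 to 5535 windows at day 3 and 740 to 3104 at day 8, and H3K4me1 from 3624 to 9173 at day 8. Human day 5 ranged from 1612 to 2621 higher and 560 to 1904 lower H3K27ac tiles and 1641 to 3662 H3K4me3 tiles. Human day 15 ranged from 190 to 1601 higher and 329 to 1340 lower H3K27ac tiles, 153 to 2886 H3K4me1 and 7 to 624 H3K4me3 tiles.

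Not run were the overlap of changed genes between species with the block or 10 kb flanks, and motif densities with a stricter score.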

Other observations

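The list of interferon-stimulated genes was added after the largest falls were seen, and what it should show was written before its values were computed. The other lists were fixed beforehand.

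Interferon-stimulated genes lost H3K27ac together between mouse naive cells and day 3 of culture, which contained an antibody to IFN-γ. Of 25 genes tested 19 fell and 1 rose (20 and 1 adjusted over the list alone), and the falls numbered 17 to 20 over the other settings. With a library left out the median log2 change of the list lay between -1.57 and -1.34. The chemokine gene Cxcl10 changed by -4.98 on the log2 scale, the antiviral genes Ifit3 by -3.36, Oas1a by -3.09, Oasl2 by -2.93 and Rsad2 by -2.54, Isg15, a ubiquitin-like modifier, by -2.25 and the factor gene Irf7 by -1.50, while Zbp1 rose by 0.42, a call lost without day 3 replicate 1 or 2 or naive replicate 2, with equal covered length, with narrower windows, with a stricter score and without centring. Neighbours such as Ifit1, Ifit2 and Ifit3 share peaks, and the 25 genes lie in 20 distinct windows, of which 14 had all members lower.

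From day 3 to day 8, 12 of the 25 genes rose, 1 of which, Gbp2, had not passed at day 3 (adjusted p = 0.053), and 3 fell. Over all settings and left-out libraries the rises numbered 7, with equal covered length, to 13, without centring. The falls numbered 1 without day 3 replicate 1 or day 8 replicate 2, and none passed with a stricter score or without centring. Cxcl10 changed by 3.45, Ifit3 by 2.03, Rsad2 by 1.82, Ifit2 by 1.30, Irf7 by 1.15, Oasl2 by 0.85 and Isg15 by 0.76, and Ifih1 (-0.64) and Stat2 (-0.52) were among the 3 falls.

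The hypothesis that interferon-stimulated genes as a group lose H3K27ac from naive to day 3 had a median log2 change of -1.50, with camera p = 1.24e-07 and 0.00897 with an estimated correlation, which is consistent with a group-wide loss in these libraries, though the list was prompted by them and is no independent evidence. That the group regains H3K27ac from day 3 to day 8 is left open: the median was 0.29 with camera p = 0.00408, and 0.0614 with an estimated correlation. The estimated correlation was 0.022 against the preset 0.01, and the test with it has far fewer degrees of freedom. The higher p therefore does not show strong correlation between these genes. Whether the antibody to IFN-γ, the activation or another factor underlies the loss was not tested, since no culture without the antibody is among the samples.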
